A study of Mus musculus with 18 samples.

How the data were processed

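The series holds RNA-seq of 18 mouse libraries in 9 groups, 3 genotypes in each of 3 tissues, with 2 libraries per group. The labels name a different mouse for each library of a group, and the same 6 mice gave intestine and testes. The deposited values were raw read counts per gene, which the authors made with STAR and HTSeq on mm9, per the submitters' processing notes, with versions not given in the sources used here. Each file listed 37620 gene IDs and 5 entries that name no gene. Those entries stayed out of library sizes and tests. Relative to the sum of all entries, reads in no feature made up 9.89% to 26.0%, reads without a unique alignment 15.3% to 29.1% and ambiguous reads 2.21% to 4.17%. Symbols were taken by gene ID from a GENCODE M21 annotation of another build, GRCm38, which named 32897 IDs and served for names, gene types and gene order only. Whether counting used strand was not given, so antisense and overlapping genes cannot be told apart. Genes with near-identical copies may have had their reads divided or dropped, and their values are uncertain.

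Each tissue was fitted on its own with its 6 libraries in R 4.3.3. EdgeR 4.0.16 gave TMM factors, the filterByExpr filter, robust quasi-likelihood fits on 3 group means with 3 residual degrees of freedom, and tests of K9M and K36M against WT and against each other. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Whether a mutant's effect differed between intestine and testes was tested as an interaction over their 12 libraries, without a block for the mouse, and the block was an alternative. The pairing comes from the mice named in the labels. Deviations of the 2 mice from their group mean correlated between the tissues at 0.0529 in WT, 0.113 in K9M and -0.0605 in K36M. The samples, main tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the alternatives and closing tests that the text names as chosen after seeing the data.

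In all, 50 lists of marker and pathway genes were written from general knowledge, and those with at least 5 tested members in a tissue were tested with camera in limma 3.58.1 at a preset correlation of 0.01. The rule named, for each mutant against WT, the 6 largest rises and the 6 largest falls past the threshold with a mean log2 CPM of at least 1, both mutant libraries beyond both WT libraries and a symbol that is not a predicted model. It also named the 2 members with the smallest adjusted p of each list with a call, up to 2 abundant members of a list without one, H3f3a and H3f3b, and the 4 largest differences each way between the mutants. Some genes that the rule named are not reported here. A group with no count is given as a bound from 3 counts over the group, and a group with 1 to 3 counts as a ratio with its exact counting interval.

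The tests were run on simulated counts drawn from the real means and library sizes. Changes were set only in genes above a minimum mean count, in a single run for each setting. Recovery among genes of low count is therefore not known. For K9M against WT, the fit recovered 66% of 2-fold and 88.9% of 4-fold changes in bone marrow (13955 genes tested), 22% and 72% in intestine (13303) and 51% and 95% in testes (18566). False calls were 14.4%, 7.84% and 11.0% of all calls, above the nominal 5%, so the counts of calls may hold more false ones than the threshold states. For the K9M interaction (19516 genes tested), the fit recovered 3% and 71% with 3 false calls, and with the mouse as a block 7% and 80% with 26 false calls. These libraries were simulated without an effect of the mouse. The simulation therefore cannot show what leaving out the block costs in paired data. Counts per library were 17114164 to 21417915 in bone marrow, 13396303 to 20577661 in intestine and 16122101 to 20993726 in testes, but depth alone did not set the precision. Replicate pairs differed by more than counting noise, with a chi-square per degree of freedom from 2.26 in testes WT to 59.1 in intestine K36M.

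Alternatives covered DESeq2 1.42.0, limma-voom and a fit without robust estimation. They also covered other scaling, other filters on low counts, an adjusted p of 0.01, a 2-fold minimum, the 2 genotypes alone, all 18 libraries together, each library left out in turn, and genes on the Y chromosome with Xist and Tsix left out. When a library was left out, the lone library of its group was assumed to vary like the other groups. Bone marrow libraries were high in Xist and those of the other tissues carried Y-linked transcripts, so no term for sex could be fitted. Mitochondrial mRNA counts were 0 in every library.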

Results

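The series measured polyadenylated RNA in mice carrying a doxycycline-inducible histone H3 transgene, either wild-type (WT) or with lysine 9 or lysine 36 replaced by methionine (K9M and K36M). Such lysine-to-methionine histones are known to inhibit the enzymes that methylate the same lysine. The mice, of a mixed C57B6/129 background, received 2 mg/ml doxycycline in water from an age of 6 to 8 weeks. RNA came from bone marrow cells that lacked lineage markers and carried the cKit receptor, a population of blood stem and progenitor cells, and from intestine and testes. Each of the 9 groups held 2 libraries from 2 mice. Intestine and testes came from the same 6 mice, and bone marrow from 6 others. Mice are named by group and label number (WT.1476). Counts assigned to genes ranged from 13396303 to 21417915 per library, and 18754 to 26488 genes had at least 1 count. No separate count of the transgene was used here. Values below are TMM-scaled CPM as mean ± SD over n = 2, and log2 fold changes ± SE. Genes are said to rise or fall where edgeR's quasi-likelihood test passed the Benjamini-Hochberg threshold. With 2 libraries per group no other grouping of the samples was tested, and counting intervals and floors cover counting error only.

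In bone marrow progenitors of K36M mice, genes of the granulocyte and monocyte lineage were low and erythroid genes high. Of 30 granulocyte-monocyte genes, 24 fell and none rose (27 fell when adjusted over the list alone), with a median log2 fold change of -1.70. F13a1, coagulation factor XIII A, went from 701 ± 159 CPM in WT to 59.9 ± 1.26 in K36M (log2 -3.55 ± 0.17). Csf2ra, a subunit of the GM-CSF receptor, fell by 2.27 ± 0.11 on the log2 scale, and Chil3, a chitinase-like protein of myeloid cells, fell by 6.02 ± 0.50. Among 27 erythroid genes 18 rose and none fell (18 when adjusted over the list alone), at a median of 1.38. Tfrc, the transferrin receptor, went from 378 ± 59.3 to 1002 ± 42.8 CPM, and the beta globin gene Hbb-bt from 2.01 ± 1.06 to 79.6 ± 0.334 CPM. The gene of the sorted receptor, Kit, singled out after its values were seen, fell as well, from 436 and 457 CPM in WT to 294 and 296 in K36M, so a different mix of sorted cells cannot be told apart from a change within cells.

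Mitotic genes were also higher in K36M bone marrow. Of 28, 25 rose (27 when adjusted over the list alone), with a median log2 fold change of 0.43, while of 27 DNA replication genes 8 rose and 3 fell (8 and 1 when adjusted over the list alone), at a median of 0.03. Ccnb1, which encodes cyclin B1, rose by 0.95 ± 0.07 and Mki67, a proliferation marker, by 0.66 ± 0.05. The p53 target list held 17 genes that rose and 4 that fell among 25 (17 and 4 when adjusted over the list alone), with Zmat3 at 2.44 ± 0.20 and Sesn2 at 1.57 ± 0.11. Of 29 hematopoietic stem cell genes, 17 fell and 4 rose (18 and 4 when adjusted over the list alone). Among them, the transcription factor genes Hoxb4 and Sox4 had log2 fold changes of -2.34 ± 0.16 and -1.47 ± 0.10. Among 7 tested developmental genes known as Polycomb targets, 4 rose and 1 fell (4 and 1 when adjusted over the list alone). Those that rose included the cell cycle inhibitor gene Cdkn2a, whose single WT count against 3.89 ± 0.382 CPM in K36M gave a ratio of 167 (counting interval 29.5 to 6633).

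Genes of other blood and stromal cell types moved as well in K36M bone marrow. Of 16 genes of mast cells, basophils and eosinophils, 12 fell and 1 rose (12 and 1 when adjusted over the list alone), among them the mast cell protease gene Cpa3 (-3.22 ± 0.20) and the histidine decarboxylase gene Hdc (-1.54 ± 0.10). Of 20 macrophage and dendritic cell genes, 14 fell (14 when adjusted over the list alone, with 1 that rose). The MHC class II gene H2-Aa changed by -3.37 ± 0.23 and the dendritic cell receptor gene Clec9a by -4.75 ± 0.32. H2-Aa was also lower in K9M (-3.17 ± 0.22), so its fall was not particular to K36M. T and NK cell genes had 10 falls and 1 rise among 17 (10 and 1 when adjusted over the list alone). Of 6 tested stromal genes, 3 rose and 2 fell (3 and 2 when adjusted over the list alone), the rises including the collagen genes Col1a1 (4.24 ± 0.47) and Col1a2 (2.65 ± 0.36). The largest rises included the ubiquitin ligase gene Hecw1, which had no WT count and was at least 154-fold higher in K36M (floor of 3 counts over the group), the X-linked homeobox gene Esx1, at least 90.9-fold higher, and the inflammasome gene Nlrp6 at 7.13 ± 0.22.

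EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7017 of 14604 genes in K36M against WT bone marrow, 3431 higher and 3586 lower, of which 2552 changed at least 2-fold. DESeq2 size factors gave 3564 higher and 3433 lower, and library size alone 3018 and 3993, so the balance depends on the scaling. The genes named above had adjusted p from 4.19e-06 (Nlrp6) to 0.00136 (Col1a2) in that test. Without K36M mouse 1312 the count was 4671, and of 58 named calls 2 were lost without K36M mouse 1310 and 1 without K36M mouse 1312, WT.1262 or WT.1266. Camera with a preset correlation called 9 lists, from an adjusted p of 3.23e-18 for the granulocyte-monocyte list to 0.0254 for T and NK cell genes. With an estimated correlation no list passed: adjusted p = 0.355 for granulocyte-monocyte, 0.377 for erythroid, 0.235 for mitotic, 0.244 for p53, 0.281 for stem cell, 0.235 for Polycomb target, 0.281 for mast cell, 0.244 for macrophage and 0.377 for T and NK genes. Under the preset correlation, camera lost the Polycomb target list without WT.1262 (adjusted p = 0.0662) or WT.1266 (0.0639) and the T and NK list without WT.1266 (0.0983).

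In K9M bone marrow few genes passed the test, among them several pseudogenes and MHC class II genes. By edgeR's quasi-likelihood test, 2079 of 14604 genes had an unadjusted p under 0.05, so more genes may differ than were called. Rps3a3, a ribosomal protein pseudogene, went from 2.79 ± 0.171 to 191 ± 7.78 CPM (log2 6.09 ± 0.10), while its parent gene Rps3a1 differed by -341 CPM, and Rps13-ps1 from 0.302 ± 0.0286 to 53.6 ± 0.834 CPM. Ccnb1ip1, which acts in meiotic recombination, had no WT count and was at least 128-fold higher in K9M. The sialyltransferase gene St6galnac1 had no count in K9M or K36M and was at least 174-fold lower in each than in WT, where it stood at 13.7 ± 0.201 CPM. Its neighbour St6galnac2 fell by 4.18 ± 0.25, the fibronectin gene Fn1 fell by 3.73 ± 0.43 and the pseudogene Rplp0-ps1 fell by 6.08 ± 0.37.

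Among the fixed lists, the macrophage and dendritic cell list held 4 falls among 20 genes in K9M bone marrow (7 when adjusted over the list alone), including the MHC class II gene H2-Aa at -3.17 ± 0.22 and Cd74, the invariant chain, at -2.60 ± 0.25. The list median was only -0.18, the rank form of camera did not pass (adjusted p = 0.0814), and H2-Aa, H2-Ab1 and H2-Eb1, among the falls, are neighbours on chromosome 17. Of 16 mast cell, basophil and eosinophil genes, with a median of -0.86, edgeR called 0, while 9 were lower when adjusted over the list alone, 10 lower at an unadjusted p under 0.05, 5 lower by DESeq2 and 0 by limma-voom. Stem cell genes had 3 rises among 29 (7 when adjusted over the list alone), including Cd34 at 0.53 ± 0.09 and Sox4 at 0.70 ± 0.09. B lymphoid genes had a median log2 fold change of 1.46 over 19 genes with no call from edgeR, 7 higher and 1 lower when adjusted over the list alone, and 13 higher and 1 lower at an unadjusted p under 0.05. DESeq2 called 5 of them higher and limma-voom 0. Erythroid genes had a median of -0.75 over 27 genes, with 0 calls by edgeR, 0 when adjusted over the list alone, 6 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. H3f3a fell by 0.59 ± 0.09, while H3f3b had a log2 value of -0.03 ± 0.06. Whether reads of the induced H3 transgene are counted under an H3 gene is not known, so values of H3 genes here and below may include them.

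In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 147 of 14604 genes in K9M against WT bone marrow, 86 higher and 61 lower, with adjusted p for the named genes that passed from 8.63e-08 (Rps3a3) to 0.0344 (Cd34). The count was 619 without WT.1262, 48 without K9M mouse 1362 and 28 without K9M mouse 1363, and of the 21 named calls 12 were lost without the last, 9 without K9M mouse 1362, 5 without either K36M mouse and 3 without WT.1266. Camera with a preset correlation called 12 lists, but none with an estimated one: adjusted p = 0.342 for B lymphoid, 0.48 for erythroid, 0.23 for macrophage and dendritic cell, 0.33 for mast cell and 0.23 for stem cell genes. The other 7 lists had adjusted p between 0.23 and 0.688 there. Under the preset correlation, camera lost the erythroid list without WT.1266 (adjusted p = 0.137), ribosomal protein genes without WT.1262 (0.205) or K9M mouse 1363 (0.274) and interferon-stimulated genes without K9M mouse 1362 (0.621).

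In the direct comparison of the mutants in bone marrow, 7850 genes differed, 4053 higher and 3797 lower in K9M, by edgeR's quasi-likelihood test. DESeq2 size factors gave 3845 higher and 4021 lower, and library size alone 4468 and 3396. C2cd4a, with 1 count in K9M, was higher in K36M by a count ratio of 670 (counting interval 120 to 26487), and Nlrp6 differed by -7.95 ± 0.24 on the log2 scale. Rps13-ps1 and Rps3a3 were higher in K9M by 7.64 ± 0.19 and 6.27 ± 0.10. The calls of K9M and K36M against WT shared 29 higher and 41 lower genes, against 20.2 and 14.98 for independent lists and at most 1 each way in simulated unchanged groups, and 26 genes were called in opposite directions (at most 1 in simulation). The simulated groups held no change in either mutant, so almost no gene could be called in them. Their shared and opposite counts therefore give no measure of agreement between real effects. Across genes, the log2 fold changes of the mutants correlated at r = 0.168, while unchanged groups simulated against the same WT libraries gave a mean of 0.486. The covariance exceeded the simulated one by 0.0881. An r or covariance from unchanged groups reflects the shared WT libraries alone, so neither comparison tests agreement. With 1 WT library for each mutant, an alternative chosen after seeing the data, r was 0.119 with WT.1262 for K9M, where 25 higher and 56 lower genes were shared and 27 opposite, and -0.022 with WT.1266 for K9M, where 33 and 65 were shared and 370 opposite. Whether the mutants agree in bone marrow therefore stays open.

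**Figure D1:**
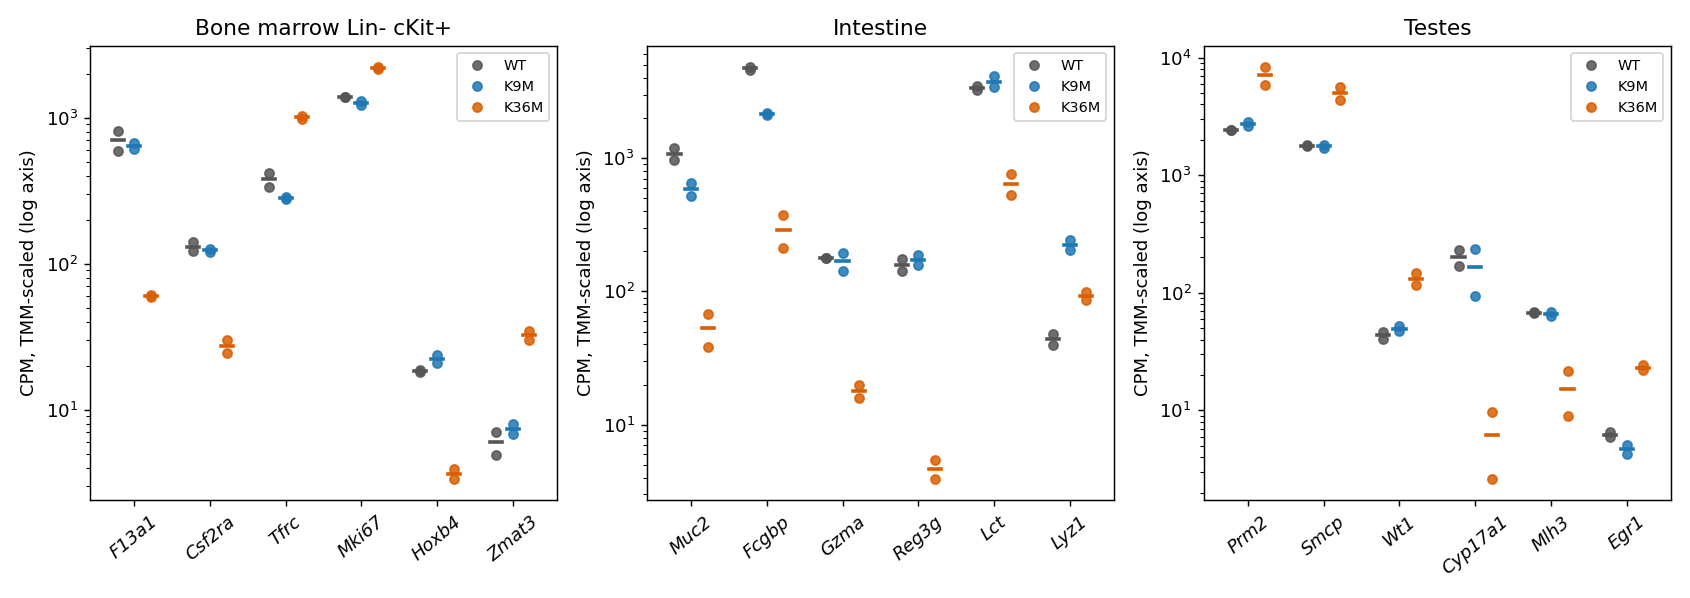
Expression of 6 named genes in each tissue, with TMM-scaled CPM on a log axis and each point a library (grey WT, blue K9M, orange K36M, 2 per group) and a bar at the group mean. F13a1 in bone marrow had a WT mean of 701 and a K36M mean of 59.9, Muc2 in intestine fell to a K36M mean of 52.8, and Prm2 in testes rose to 7111.

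In the intestine of K36M mice, genes of goblet cells, of T and NK cells and of antimicrobial defence were low. Of 19 goblet cell genes, 14 fell and 1 rose (14 and 1 when adjusted over the list alone). The mucin gene Muc2 went from 1082 ± 151 to 52.8 ± 20.6 CPM (log2 -4.35 ± 0.34) and Fcgbp, a mucus protein gene, from 4743 ± 170 to 291 ± 113 CPM. Of 18 T and NK cell genes, 17 fell (18 when adjusted over the list alone), with granzyme genes Gzma and Gzmb at -3.32 ± 0.22 and -3.51 ± 0.29. Among 16 antimicrobial and MHC class II genes of the epithelium, 9 fell (10 when adjusted over the list alone), with the antibacterial lectin gene Reg3g at -5.07 ± 0.25 and Pigr, the receptor that carries IgA into the lumen, at -2.31 ± 0.22. Lists of some other cell types had medians above 0 without a camera call, though not all held more rises than falls: fibroblast genes had 3 rises and 1 fall among 8 (3 and 1 when adjusted over the list alone) at a median of 2.75, endothelial genes 1 rise among 7 (3) at 1.35, smooth muscle genes 1 fall among 8 (1) at 1.18, and B and plasma cell genes 1 rise and 1 fall among 6 (1 and 1) at 2.03. Tuft cell genes had 3 falls and 1 rise among 15 (3 and 1). A change in the mix of cells is thus not told apart from a change within them.

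Absorptive and secretory genes moved in both directions in K36M intestine. Of 30 enterocyte genes, 8 fell and 1 rose (9 and 1 when adjusted over the list alone), with the lactase gene Lct at -2.39 ± 0.26 and the aminopeptidase gene Anpep at -1.75 ± 0.33. Of 19 enteroendocrine genes, 5 fell and 3 rose (6 and 6 when adjusted over the list alone), among them Chga at 1.68 ± 0.19, and the glucagon gene Gcg at no count in K36M, at least 42-fold lower. Of 13 Paneth cell genes, 2 rose and 2 fell (3 and 2 when adjusted over the list alone), with the lysozyme gene Lyz1 at 1.08 ± 0.18. Of 20 intestinal stem cell genes, 2 rose, Lgr5 (3.07 ± 0.67) and Igfbp4 (1.99 ± 0.51), and none did when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, went from 7.69 ± 4.55 to 266 ± 107 CPM. Serpinb9b rose from 0.174 ± 0.041 to 197 ± 18 CPM, the transcription factor gene Tfec was at least 151-fold higher from no WT count, Ret, a neurotrophic receptor gene, rose by 3.84 ± 0.22, and Dnase1 fell by 5.98 ± 0.26.

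EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3323 of 14246 genes in K36M against WT intestine, 1662 higher and 1661 lower, and the genes named had adjusted p from 0.000767 (Reg3g) to 0.0363 (Igfbp4). The count was 1008 without WT.1476, 881 without WT.1477, 1853 without K9M mouse 1516, 1790 without K9M mouse 1519 and 1890 with the 2 genotypes alone. Of 63 named calls, 23 were lost without WT.1476, 26 without WT.1477, 6 without K9M mouse 1516, 7 without K9M mouse 1519, 4 without K36M mouse 1485 and 6 without K36M mouse 1553. Camera with a preset correlation called T and NK, goblet and antimicrobial genes, and each had adjusted p = 0.476 with an estimated correlation. Intestine libraries differed in content: WT.1476 held testis transcripts at 1.01% of their testes level, against 0.1397% to 0.333% in the others, and leaving 2955 testis genes out, an alternative chosen after seeing the data, gave 3431 calls. The transcripts behind these shares were picked as nearly absent from the other intestine libraries, so the low shares of the others are partly built in. Mitotic genes summed to 430 and 157 CPM in WT and to 90.7 and 424 CPM in K36M, so that within-group spread was large for them.

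In K9M intestine, few genes passed the test, while 1469 of 14246 had an unadjusted p under 0.05 by edgeR's quasi-likelihood test. Lyz1 rose from 43.9 ± 5.72 to 223 ± 26.0 CPM (log2 2.35 ± 0.18), Eno1b, a near copy of the enolase gene Eno1, from 1.30 ± 0.465 to 114 ± 17.5 CPM, and Bglap3, of the osteocalcin family, from 1.95 ± 1.18 to 216 ± 11.4 CPM. Fzd8, a Wnt receptor gene, had no K9M count and was at least 33.0-fold lower, and Aldh1l1, of folate metabolism, fell by 2.78 ± 0.33. Goblet cell genes had a median log2 fold change of -0.90 over 19 genes and antimicrobial and MHC class II genes one of -1.50 over 16, each with 0 calls by edgeR. When adjusted over the list alone, 4 goblet genes were lower and 1 higher and 7 antimicrobial genes were lower, while 12 and 8 were lower at an unadjusted p under 0.05. DESeq2 called 4 and 7 of them lower and limma-voom 0. The shift was not particular to these lists. Camera with a preset correlation, though for none of them with an estimated one (adjusted p from 0.724 to 0.78), also put mitotic (median -1.44), interferon-stimulated (-0.74), DNA replication (-0.59), cytosolic ribosomal protein (-0.49, adjusted p = 3.77e-11) and macrophage and dendritic cell genes (-0.16) lower, and endothelial genes (1.03) higher.

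The count in K9M against WT intestine was 30 of 14246 genes, 21 higher and 9 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 0.00409 (Eno1b) to 0.0497 (Atp6v0e2). It was 3 without WT.1476, 3 without WT.1477, 1 without K9M mouse 1519, 131 without K36M mouse 1485, 141 without K36M mouse 1553 and 202 with the 2 genotypes alone. Without K9M mouse 1516 it was 0 by edgeR, where 818 genes had an unadjusted p under 0.05; no other tool was run on that subset. Of 13 named calls, 13 were lost without K9M mouse 1516, 12 without K9M mouse 1519 and 11 without WT.1476 or WT.1477. Camera called 8 lists with a preset correlation, of which the goblet and antimicrobial lists had adjusted p = 0.724 and 0.713 with an estimated one, and the other 6 lay between 0.724 and 0.78. DNA replication genes lost the preset camera call without WT.1476 (adjusted p = 0.693) or K9M mouse 1516 (0.115), and endothelial genes without WT.1477 (0.108).

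K9M and K36M differed in 3570 genes in intestine, 1834 higher and 1736 lower in K9M, by edgeR's quasi-likelihood test; the count was 640 without K9M mouse 1516 and 620 without K9M mouse 1519. Scaling by library size alone gave 1402 higher and 2052 lower. Gcg was at least 45.5-fold higher in K9M, and the beta-adrenergic receptor gene Adrb3, with no K9M count, at least 219-fold lower. Calls against WT shared 15 higher and 5 lower genes between the mutants, where independent lists would share 2.45 and 1.05. Their log2 fold changes correlated at r = 0.243 across genes, against 0.496 in simulated unchanged groups, with a covariance 0.195 above the simulated one, and 3 genes were called in opposite directions (0 in simulation). As in bone marrow, the simulation held no change in either mutant, so its r and counts cannot show agreement. With 1 WT library for each mutant r was -0.0187 with WT.1476 for K9M and 0.215 with WT.1477 for K9M, so agreement stays open here too.

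**Figure D2:**
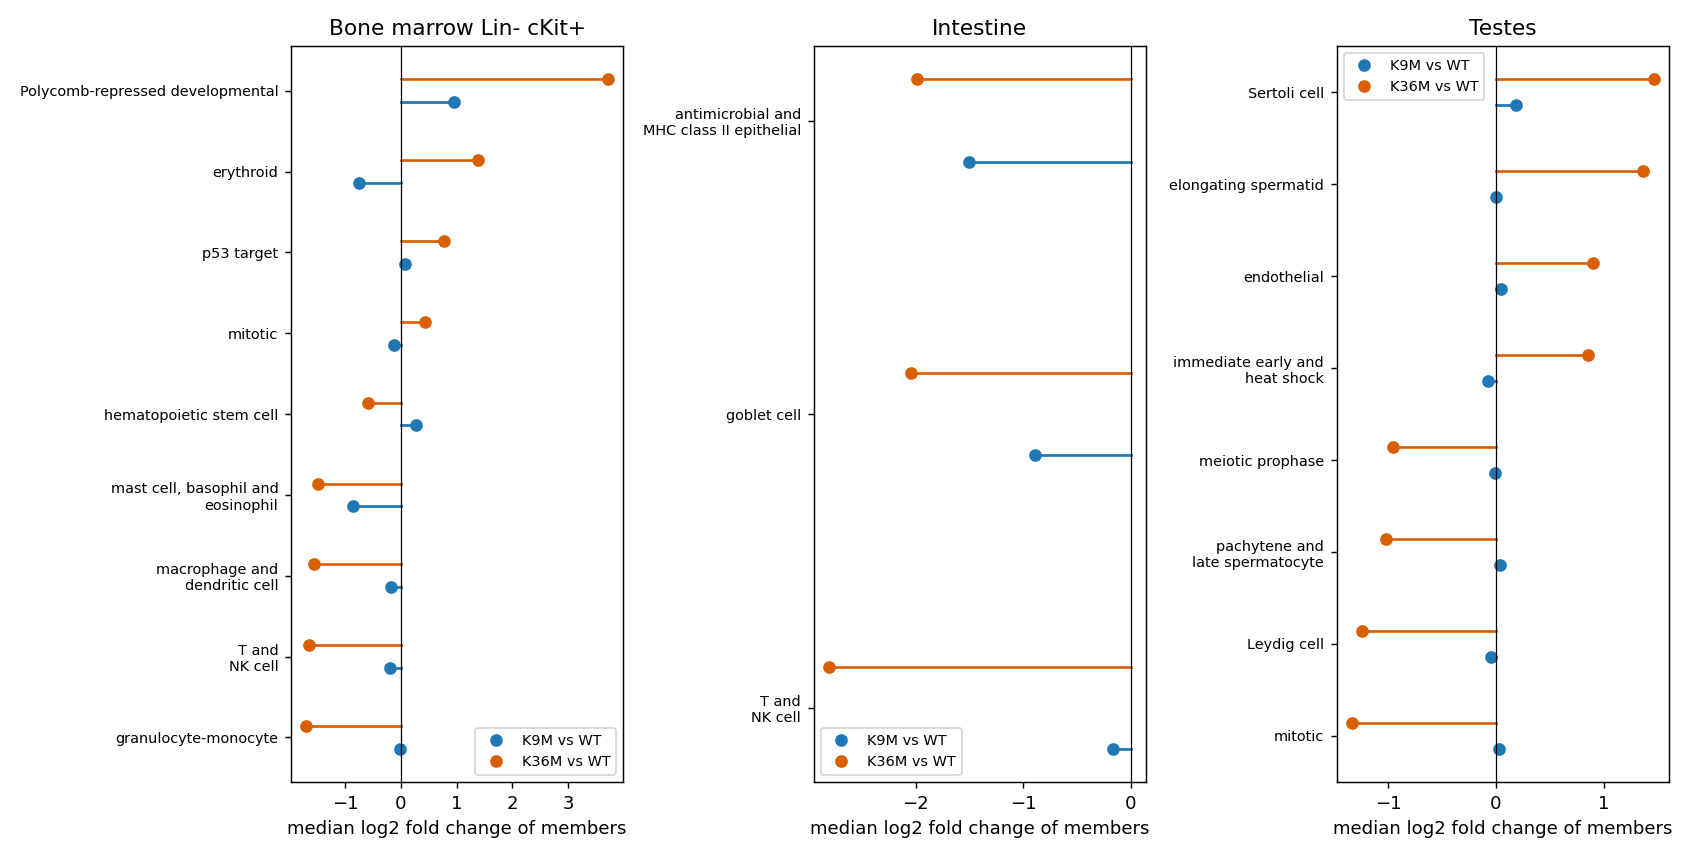
Median log2 fold change against WT of the members of each gene list that camera with a preset correlation called in K36M, in each tissue, with blue points for K9M and orange points for K36M and lines drawn from 0. Granulocyte-monocyte genes in bone marrow stood at -1.70, goblet cell genes in intestine at -2.04 and elongating spermatid genes in testes at 1.36 in K36M.

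In the testes of K36M mice, genes of late spermatids and of Sertoli cells were high, and genes of meiosis and division and most called Leydig cell genes low. All 23 elongating spermatid genes rose (23 when adjusted over the list alone), with a median log2 fold change of 1.36. The protamine gene Prm2 went from 2418 ± 3.05 to 7111 ± 1815 CPM and Smcp, of the sperm mitochondrial sheath, from 1788 ± 37.4 to 4981 ± 894 CPM. Of 20 Sertoli cell genes, 17 rose (17 when adjusted over the list alone), including the transcription factor genes Wt1 (1.60 ± 0.16) and Gata4 (1.24 ± 0.13). Leydig cell genes had 8 falls and 2 rises among 14 (8 and 2 when adjusted over the list alone), and the steroidogenic enzyme genes Cyp17a1 and Cyp11a1 changed by -5.02 ± 0.72 and -3.84 ± 0.53.

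Meiotic and mitotic genes of K36M testes were lower. Of 28 meiotic prophase genes, 20 fell and 1 rose (20 and 1 when adjusted over the list alone), with the mismatch repair gene Mlh3 at -2.14 ± 0.37 and Syce2, of the synaptonemal complex, at 1.08 ± 0.13. Of 24 pachytene and late spermatocyte genes, 14 fell and 3 rose (14 and 3 when adjusted over the list alone), including Pou5f2 at -2.77 ± 0.43. Of 28 mitotic genes, 21 fell (24 when adjusted over the list alone), with the kinesin gene Kif11 at -1.98 ± 0.34. Round spermatid genes were divided, with 7 rises and 6 falls among 25 (7 and 7 when adjusted over the list alone). Immediate early and heat shock genes held 11 rises and 2 falls among 22 (11 and 2 when adjusted over the list alone), such as Egr1 at 1.89 ± 0.16 and Ier3 at 2.42 ± 0.24. Of 11 endothelial genes, 7 rose (7 when adjusted over the list alone), with Esam at 1.98 ± 0.22. Without a camera call, the median was 0.51 for smooth muscle genes, 0.38 for macrophage and dendritic cell genes and -0.21 for fibroblast genes. The kallikrein genes Klk1b24, Klk1b27 and Klk1b21, near copies whose reads can be split, had log2 values of -5.75 ± 0.40, -5.19 ± 0.56 and -4.27 ± 0.28, and H3f3b fell by 0.71 ± 0.17.

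EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 9476 of 19160 genes in K36M against WT testes, 4921 higher and 4555 lower, with adjusted p for the genes named from 0.00241 (Wt1) to 0.016 (H3f3b). The count was 2310 without WT.1476 and 2498 without WT.1477, and of 58 named calls 13 and 12 were lost without these and 2 without either K36M mouse. Camera called 8 lists, none of them with an estimated correlation: adjusted p = 0.654 for elongating spermatid, Sertoli, meiotic, pachytene and mitotic genes, 0.675 for Leydig, 0.471 for endothelial and 0.468 for immediate early genes. Under the preset correlation, camera lost the Leydig list without K36M mouse 1485 (adjusted p = 0.261) or 1553 (0.0584), and the immediate early and endothelial lists without mouse 1485 (0.135 and 0.186). The K36M libraries lay at 56.2 and 121 on the first principal component, whereas WT and K9M lay between -46.4 and -41.2. Scaling by library size alone moved the median of all genes from 0.02 to -0.12 and turned the balance to 4001 higher and 5291 lower, while an adjusted p of 0.01 gave 2590 higher and 1567 lower, so neither direction can be said to prevail.

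The germ cell lists of K9M testes held no called change at this depth and number of mice. In the spermatogonial, meiotic prophase, pachytene, round spermatid and elongating spermatid lists, 0 genes passed edgeR's test, 0 when adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom, with medians between -0.03 and 0.07. These fits shared their spread with the K36M pair, whose chi-square per degree of freedom was 43.0, against 2.26 in WT and 4.54 in K9M. By edgeR, 539 of all genes had an unadjusted p under 0.05, against 2112 with the 2 genotypes alone. The lists were not tested in that fit, so smaller changes may be missed. Rises were led by Zfp990 (6.42 ± 0.35), a clustered zinc finger gene, Rps13-ps1 (7.42 ± 0.57), the potassium channel subunit gene Kcnab2 (1.58 ± 0.12) and Ccdc7a (1.26 ± 0.12). Falls were led by the taste receptor gene Tas1r1 (-3.74 ± 0.20), Zfp979 (-3.46 ± 0.30), Zfp980 (-2.63 ± 0.26), the transporter gene Abca6 (-2.25 ± 0.15) and Znf41-ps (-1.61 ± 0.16). Sertoli cell genes had a median of 0.19 over 20 genes with 0 calls by edgeR, 0 when adjusted over the list alone, 2 higher at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom.

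Only 13 of 19160 genes passed in K9M against WT testes, 5 higher and 8 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 0.00268 (Zfp990) to 0.0367 (Zfp980). The count was 2 without each of WT.1476, WT.1477 and K9M mouse 1519, 243 without K36M mouse 1485, 247 without K36M mouse 1553 and 213 with the 2 genotypes alone. Without K9M mouse 1516 it was 0 by edgeR, with 346 genes at an unadjusted p under 0.05 and no other tool run on that subset. Of 9 named calls, 9 were lost without K9M mouse 1516, 8 without K9M mouse 1519, WT.1476 or WT.1477, and 1 without either K36M mouse. Camera called the Sertoli list, with adjusted p = 0.983 given an estimated correlation and 0.206 without K9M mouse 1519 under the preset one.

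The mutants differed in 9430 genes in testes, 4571 higher and 4859 lower in K9M, by edgeR's quasi-likelihood test. Scaling by library size alone turned this to 5271 higher and 3930 lower. Cyp17a1 and Klk1b24 were higher in K9M by 4.73 ± 0.71 and 5.22 ± 0.41, and the glycosyltransferase gene Galnt15 differed by -4.28 ± 0.21. The count was 2065 without K9M mouse 1519 and 0 without K9M mouse 1516, where 7797 genes had an unadjusted p under 0.05 and no other tool was run. Calls against WT shared 0 higher and 5 lower genes between the mutants, against 1.28 and 1.90 for independent lists, and across genes r was 0.188 against a simulated 0.501, with a covariance 0.0166 above the simulated one, and 2 genes were called in opposite directions (0 in simulation). Here too the simulation held no change, so its r and counts cannot show whether the mutants agree in testes. With 1 WT library for each mutant r was 0.0822 with WT.1476 for K9M and 0.0473 with WT.1477 for K9M.

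Across tissues, 158 genes rose and 161 fell in K36M in all 3 tissues. No number for independent lists was computed for these. With 48.0% of tested genes called in bone marrow, 23.3% in intestine and 49.5% in testes, many would coincide without a common response. Bone marrow and intestine shared 419 rises and 603 falls, against 321 and 354 for independent lists, while 206 rose in bone marrow and fell in intestine and 295 did the reverse. Intestine and testes shared 584 and 414, against 426 and 354, while 243 rose in intestine and fell in testes and 383 did the reverse. Bone marrow and testes shared 928 rises and 705 falls, against 905 and 782, fewer in all than the 854 that rose in bone marrow and fell in testes and the 1069 that did the reverse, and their log2 fold changes correlated at r = -0.0095. In K9M, Rps13-ps1 rose in all 3 tissues, and Gm8730, a predicted gene singled out after its values were seen, fell in all 3. Gm8730 also fell in K36M in each tissue.

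Whether a mutant's effect differed between intestine and testes of the same mice was tested as an interaction. For K36M, 4552 of 20253 genes differed, 2046 more positive and 2506 more negative in intestine, and with the mouse as a block the count was 2968, of which 2846 were shared. Muc2 changed by -4.35 ± 0.34 in intestine, with a difference from testes of -4.97 ± 0.46, and Rrm2 differed by 5.88 ± 0.60. Without the intestine library of WT.1477 there were 1120 more positive and 3162 more negative genes, and without that of WT.1476 1536 and 1943. The K36M count was 2205 without the testes library of WT.1476 and 2221 without that of WT.1477. Scaling by library size alone gave 2429 more positive and 1724 more negative genes.

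For K9M, 25 genes differed by the same edgeR quasi-likelihood test and 6 with the mouse as a block, all of them among the 25, led by Cmya5, a muscle protein gene, at a difference of 9.21 ± 0.59. Leaving out the intestine library of WT.1477, so that WT.1476 with its testis transcripts stood alone for intestine WT, gave 671 genes, 631 of them more negative in intestine. The count was 7 without that of WT.1476, 2 and 8 without the intestine library of K9M mice 1516 and 1519, 44 without the intestine library of K36M mouse 1553, 1 without the testes library of WT.1476, of WT.1477 or of K9M mouse 1516, 2 without that of K9M mouse 1519, and 14 without that of K36M mouse 1485 or 1553.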

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

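Of the tests that weigh explanations here, those on K36M testes were chosen only after the result was seen, and those on testis transcripts before. Genes are given because a mutant's effect differed between intestine and testes of the same mice by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or because lists moved oppositely. Values are log2 differences, intestine minus testes, and those of genes with a group at 0 counts depend on the prior count and are no bounds.

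For K9M, 25 genes differed. Of the named genes, the muscle protein gene Cmya5 (9.21), the receptor-like gene Nradd (4.94) and Eno1b (4.26) were more positive in intestine. Fzd8 (-9.45), Fbxo44 (-3.23), Hykk (-3.18), Aldh1l1 (-2.93), Atp6v0e2 (-2.06) and Kcnab2 (-1.88) were more negative there. With the mouse as a block, Cmya5, Nradd, Eno1b and Aldh1l1 stayed past the threshold. Fzd8, Fbxo44, Hykk, Atp6v0e2 and Kcnab2 did not, with differences of -9.45, -3.25, -3.18, -2.06 and -1.88 and adjusted p of 0.404, 0.392, 0.424, 0.404 and 0.424.

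For K36M, 4552 genes differed, of which 2846 stayed past the threshold with the mouse as a block. Which of the genes named below stayed is not given here. Among genes of epithelium and immune cells, Muc2 (-4.97), Fcgbp (-3.30), Car4 (-4.73), Anpep (-2.48), Pigr (-2.43), Cd24a (-2.18), Gzma (-3.16), H2-Eb1 (-3.05), Ighm (-2.39) and Ptprc (-1.91) were more negative in intestine. Lgr5 (2.26), Pnliprp2 (4.30), Chga (0.94), Csf1r (3.65) and Cxcl10 (3.23) were more positive there. Of the named stromal, vascular and neural genes, Pdgfra (3.88), Col3a1 (4.94), Flt1 (4.97), Apln (3.51), Ret (2.88), S100b (5.54) and Sema3e (9.51) were more positive in intestine, while Mylk (-1.80), Smtn (-1.26) and Fbln1 (-1.14) went the other way. Developmental, germline and imprinted genes more positive in intestine were Lhx1 (3.60), Wnt1 (5.23), Hoxb9 (5.57), Piwil2 (5.76), Ctcfl (4.99), Sgce (7.79) and Meg3 (2.45), and Impact (-1.24) was more negative.

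Chromatin and zinc finger genes that differed for K36M were Kdm3a (2.03), Aebp2 (0.86), Zfp809 (1.25) and Zfp820 (2.79), and in the negative direction Jarid2 (-1.53), Kdm4b (-1.22) and Zfp950 (-3.60). Replication and stress genes were Rrm2 (5.88), Pcna (1.38) and Dusp1 (2.33) against Fos (-1.88), Ier3 (-2.97), Sesn1 (-2.23) and Tnfrsf10b (-1.82). Genes of the testis were Wt1 (-8.10), Gata4 (-1.31), Syce2 (-1.99), Etv5 (-1.14), Actrt1 (-4.03), Cst8 (-4.26) and Armc2 (-5.52), with Klk1b27 (6.595) positive. Of these, Wt1, Actrt1, Cst8 and Klk1b27 did not pass the count filter of the intestine fit. Testis transcripts in the intestine library of WT.1476 can make such genes look lower in K36M intestine. The interaction was not rerun without testis genes. Other genes were Serpinb9b (10.52), Barx2 (-7.32) and Dnase1 (-5.08). Barx2 here and Gzma above did not pass the count filter of the testes fit.

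Mitotic genes moved oppositely in K36M, with a median log2 fold change of 0.43 in bone marrow and -1.34 in testes. In testes the medians of the mutant libraries were far apart, at -0.80 in K36M mouse 1485 and -2.10 in K36M mouse 1553. The difference between the tissues, which came from different mice, was not tested.

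The cell type lists of K36M testes moved apart, with elongating spermatid and Sertoli genes high and mitotic, meiotic and Leydig genes low. A loss of dividing and meiotic germ cells alone would raise every other cell type alike. Against it, the Sertoli medians of the K36M libraries were 1.16 and 1.67 and the Leydig medians -0.88 and -1.58, where any WT and K9M libraries differed by at most 0.24 and 0.62, and the Sertoli median of the fit exceeded the Leydig one by 2.70. A pattern carried by 1 of the K36M libraries would leave the other within the range of the unchanged libraries. For all 5 lists both K36M libraries lay beyond the largest median difference between any WT and K9M libraries, nearest for Leydig genes, and K36M mouse 1553 moved further than mouse 1485 in each. However, all 9476 genes called in K36M testes had both K36M libraries beyond both WT libraries, and the lists were picked after their calls were seen. The check could thus hardly fail, and it shows only that both libraries moved the same way. A change of Leydig cells beside that of germ cells, and a difference in how the tissue was handled, stay open and were not tested.

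The intestine library of WT.1476 held testis transcripts at 1.01% of their testes level over 200 abundant testis genes. These genes had a mean in the other intestine libraries under 1% of their WT testes level, with no such bound on this library. Their levels in that library followed those in testes across genes (Spearman rho 0.573), in line with testis RNA or cells carried into it, although K36M mouse 1485 also reached a rho of 0.506. For misassigned indexes between libraries, the testes library of the same mouse held intestine genes at 0.142 times that share. This passed the bound of 0.1 set before, but the bound left out the background of the other testes libraries, which held intestine genes at 0.136% to 0.165% of their intestine level against 0.144% in that library, so exchange of reads cannot be told apart from none. Leaving out 2955 testis genes, an alternative chosen after seeing the data, gave 38 calls for K9M and 3431 for K36M in intestine.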

How the results depend on the processing

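The alternatives without testis genes, with protein-coding genes only and with 1 WT library for each mutant were chosen after seeing the data. Of the named gene values under alternatives, 3905 of 4234 kept direction and side of the threshold, 324 lost the call, 2 gained it and 3 reversed, and 187 of 228 marker sums moved by less than their spread. Among lists called by camera with a preset correlation, fry kept 6 of 12 in K9M bone marrow. It kept 2 of 3 in K36M and 0 of 8 in K9M intestine, and 3 of 8 in K36M and 0 of 1 in K9M testes. For K9M, the bone marrow count was 463 with no filter on low counts, 352 by DESeq2 and 46 at an adjusted p of 0.01. The intestine count was 1180 with no filter, 372 by DESeq2, 1 at 0.01, 202 with the 2 genotypes alone and 453 with all 18 libraries. The testes count was 37 with no filter, 46 by DESeq2, 6 at 0.01, 213 with the 2 genotypes alone and 6 with protein-coding genes only. The K9M difference between tissues was 54 with no filter, 149 by DESeq2, 46 by limma-voom and 5 at 0.01. For K36M, a 2-fold minimum gave 2552 in bone marrow and 5028 in testes, and 0.01 gave 4499 in bone marrow, 927 in intestine, 4157 in testes and 1855 for the difference between tissues, both by construction. The 2 genotypes alone gave 1890 in intestine, and all 18 libraries gave 3635 in bone marrow and 5910 in intestine. Between the mutants, a 2-fold minimum gave 3030 in bone marrow and 4880 in testes, 0.01 gave 1023 in intestine and 4055 in testes, and all 18 libraries gave 4482 in bone marrow and 6090 in intestine. Apart from the stricter thresholds, the cause was not tested. Leaving out each library in turn gave 28 to 619 calls for K9M and 4671 to 6861 for K36M in bone marrow, 0 to 141 and 881 to 3775 in intestine, and 0 to 247 and 2310 to 12934 in testes. Between the mutants it gave 5432 to 8403 in bone marrow, 620 to 3972 in intestine and 0 to 12901 in testes, and for the difference between tissues 1 to 671 for K9M and 2205 to 5407 for K36M. The uncalled value of H3f3b reversed in K9M bone marrow without K9M mouse 1363 (0.0343, from -0.0897 without K9M mouse 1362) and in K9M testes without WT.1476 (-0.00703) or K9M mouse 1519 (-0.00409), against a highest of 0.0512 without WT.1477. Interferon-stimulated genes in K9M bone marrow, lower by camera with a preset correlation (adjusted p = 0.0244, and 0.688 with an estimated one), turned higher without WT.1262 (adjusted p = 0.109), within a leave-one-out range from 1.53e-13 without WT.1266 to 0.621 without K9M mouse 1362. The cause was not tested.

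With the mouse as a replicate block, 6 genes differed between tissues for K9M, all among the 25, and 2968 for K36M, of which 2846 were shared. No other result could take the block, since each mouse gave 1 library per tissue.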

Other observations

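The tests of neighbouring genes, of mice far apart, of BC018473 and of processed pseudogenes were chosen only after the result was seen. Lists of chromatin genes were divided in K36M. In bone marrow 9 rose and 4 fell of 23 genes of H3 K9 methylation (9 and 4 when adjusted over the list alone), 5 and 5 of 16 of H3 K36 methylation (5 and 5) and 4 and 3 of 11 of Polycomb complex 2 (4 and 3), and camera called none (adjusted p = 0.507, 0.899 and 0.899), while fry, which does not compare with other genes, passed the first as higher and the third as lower (0.0264, 0.704 and 0.0126). In intestine it was 2 and 1 of 23, 2 and 1 of 16, and 1 and 2 of 10, the same when adjusted over the list alone (camera adjusted p = 0.832, 0.832 and 0.836, fry 0.514 for each). In testes more fell, 12 against 3 rises of 24, 7 against 4 of 16, and 4 against 1 of 10, the same when adjusted over the list alone (camera adjusted p = 0.212, 0.675 and 0.538, fry 0.0771, 0.117 and 0.221). Among KRAB and clustered zinc finger genes, 47 fell and 14 rose of 125 in bone marrow (47 and 14 when adjusted over the list alone), 22 and 7 of 110 in intestine (30 and 8 when adjusted over the list alone) and 33 and 17 of 132 in testes (28 and 15 when adjusted over the list alone). Camera called none of these zinc finger lists (adjusted p = 0.0655, 0.0538 and 0.519), its rank form passed bone marrow and intestine as lower (0.00793, 0.0124 and 0.570), and fry bone marrow alone (0.00864, 0.0533 and 0.0927), so the result depends on the test.

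In K9M bone marrow, 4 of the 125 zinc finger genes rose (5 when adjusted over the list alone), among them Zfp868 (0.77 ± 0.09) and Zfp992 (1.29 ± 0.19). Of 16 germline genes, 1 rose, Stag3, of meiotic cohesin (1.27 ± 0.17), and 5 when adjusted over the list alone. Camera called both lists with a preset correlation (adjusted p = 0.00141 and 0.00023) and neither with an estimated one (0.342 and 0.32). In K36M, germline genes of intestine had 5 rises and 1 fall among 19 (5 and 1 when adjusted over the list alone), with Piwil2 at 4.09 ± 0.30, but a median of -0.23, and Polycomb targets 6 rises and 3 falls among 14 (7 and 3 when adjusted over the list alone). Camera called neither (adjusted p = 0.429 and 0.343).

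Genes called in K9M neighbour each other along the chromosomes. In bone marrow 36 of 139 placed calls had another called gene within 10 tested places, against a mean of 24.7 and a 95th percentile of 35 in random sets (permutation p = 0.0429). In testes it was 3 of 11 (95th percentile 2, permutation p = 0.0023), with 6 of the 11 on chromosome 4 (adjusted p = 0.00246). Linked blocks of strain alleles or of the inserted transgenes would give both. The random sets do not account for neighbours of related sequence or shared regulation, so the test cannot separate these from linkage. In bone marrow the called neighbours include H2-Aa, H2-Ab1, H2-Eb1, H2-Q6 and H2-Q7 on chromosome 17 and Akr1c12 and Akr1c13 on chromosome 13. In testes they are Zfp990, Zfp980 and Znf41-ps. In intestine, 2 of 29 against a 95th percentile of 4 leaves this open at so few calls. The H2 and Akr1c genes named here also passed in K36M bone marrow, in the same direction as in K9M. Among the called neighbours, Cela1, Cd1d2 and Trim68 passed in opposite directions. Neighbours and pseudogenes were tested for K9M calls only, so linked alleles stay open for K36M as well.

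Other explanations of these neighbours stay open. Derepression of clustered genes by K9M would raise them, and 21 of 41 were lower, near an even split, while random sets alone would give many such neighbours. The block on chromosome 11 with St6galnac1, St6galnac2 and BC018473, a gene singled out after its values were seen, was low in both mutants. In bone marrow BC018473 stood at 222 and 190 CPM in WT. In intestine and testes 1 of 4 WT libraries was at or below the highest mutant library, and the gene differed between the WT mice in the same direction in both tissues (0.73 CPM in WT.1476 and 8.00 in WT.1477 in intestine, 0.060 and 0.891 in testes). This is in line with an allele, and mutant H3 does not explain a difference between WT mice, but lower expression through mutant H3 beside it stays open. Among genes 8-fold apart between the mice of a group in both tissues, the same mouse was higher for 6 of 6 (exact binomial p = 0.0313), but 2 are hemoglobin genes open to blood content, and the other 4 of 4 cannot pass (exact binomial p = 0.125). Processed pseudogenes were 15 of 174 placed K9M calls, 8.62% against 4.72% of tested genes (one-sided exact Fisher p = 0.0180). By tissue they were 14 of 139 in bone marrow and 3 of 11 in testes (one-sided exact Fisher p = 0.000243 and 0.00700), and 2 of 29 in intestine, which did not pass (one-sided exact Fisher p = 0.13996). This is in line with reads shared with parent genes, where Rps3a3 rose by 188 CPM as Rps3a1 changed by -341 CPM in bone marrow. In intestine and testes Rps3a3 was not called, and the gain lay in 1 of the K9M mice (9.36 ± 12.0 and 6.61 ± 8.58 CPM), where Rps3a1 changed by -43.3 and -3.92 CPM, so an allele carried by some mice stays open.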
